A study of Mus musculus with 6 samples.

How the data were processed

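Gene counts from RNA sequencing of differentiated mouse C2C12 cells were analysed as the authors deposited them. The table holds whole-number read counts per gene row and library, not normalized, with 1 column for each of the 6 libraries, 3 untreated and 3 treated with 1 µM lenvatinib. Group and replicate number came from the sample titles, and each count column was matched to a sample by name. Per the labels' protocols, total RNA was isolated with a column kit and reads were aligned with Hisat2 2.0.1. Per the submitters' processing notes, HTSeq 0.6.1 and the build mm10 were used. The library kit, the selection of mRNA, the read filters and the strand setting of the counting are not given in the sources used here. A deposited column of feature length in bases (unit other, with no normalization) served only for checks of length.

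The table has 56792 gene rows, 53519 with an Ensembl identifier and 3273 without one, and holds no row of unassigned reads. Its positions are not those of mm10: of 51863 identifiers shared with the GENCODE M21 annotation of GRCm38, 1542 (3%) have the same start and end, and 6 scaffold names are missing there. Positions are therefore printed as deposited, without a build, and were not combined with the reference genome. In 585 rows, 319 of them tested, the feature length exceeds the span of the gene, so such a row may also hold reads from outside the gene; the counting behind it was not tested. The row of mt-Co1 is of this kind (feature length 8238 against a span of 1545 bases), and the rows of most other mitochondrial genes are at 0, so mitochondrial genes were not interpreted. These wide rows hold 1.59 to 1.72% of the counts per library and the rows without an Ensembl identifier 0.208 to 0.265%. A few fixed genes, Acta1 among them, were not analysed here.

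Library totals were 26597093, 25529288 and 28886472 counts in the untreated and 24585849, 24566768 and 32406563 counts in the lenvatinib libraries, and 3 counts correspond to 0.0926 to 0.122 CPM. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared before use. The chi-square per degree of freedom over genes with at least 20 summed counts was 2.8 to 5.66 within groups, above sampling noise, so no library was a copy of another.

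The comparison used the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation, then glmQLFTest) in R 4.3.3, with TMM factors (0.996 to 1.007). Rows were kept by filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 14989. Benjamini-Hochberg adjusted p-values under 0.05 were called. The biological coefficient of variation was 3.6%. The CPM, the log2 fold changes and the fold values printed were computed here from the deposited counts, and the SE of a fold change was derived from the quasi-likelihood F statistic. For principal components log2 CPM with a prior count of 2 was used over the 10002 genes above a mean log2 CPM of 3.

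Before the data were examined, 48 gene lists were fixed for pathways, complexes and cell type markers that fit muscle cells and this drug. The 43 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), Benjamini-Hochberg adjusted over these lists, and again with the correlation estimated per list and with fry. Camera asks whether a list's genes move against the other genes. Counts of members that rose or fell use the adjustment over all tested rows, with the adjustment over the list alone beside it.

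The genes named in the text were chosen by a rule fixed at the same time. It takes the 10 rising and 10 falling genes with the largest fold change among those past the threshold, with a mean of at least 5 CPM in the higher group, every lenvatinib library beyond every untreated one, and a symbol other than Gm or LOC with digits, a Rik clone or a pseudogene. It adds the 5 genes with the smallest p in each direction under the same conditions, the target kinases, 15 fixed muscle and metabolic genes, and up to 4 members per list with the smallest p. Other genes are marked as chosen after their values were seen. A few genes that the rule picked, 1 of the 10 largest falls among them, are not reported here.

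In total 22 alternatives were run, 19 of them fixed beforehand; gene counts were recomputed under 20 of them, and the count of lists and each named gene and list under up to 17. The planned ones were other scalings, filters and thresholds, DESeq2 1.42.0, limma-voom, an estimated correlation, fry, the replicate number as a block, and leaving out each library. The other 3 were added after seeing the data: without rows wider than the gene, with named genes only, and with a correction for GC content and length. The correction removes, per library, the lowess trend of log2 CPM on transcript GC content and on feature length. GC content came from the longest GENCODE M21 transcript and was found for 97.1% of tested rows. The direction of an uncalled list is that of camera.

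The scripts were tested on simulated counts for the lenvatinib and untreated comparison with 14817 genes tested and 200 genes changed. The members of a further list also held planted changes. The test recovered 10.4% of genes changed 1.1-fold, 48% of those changed 1.2-fold, 78% at 1.5-fold and 89.8% at 2-fold. Of the simulated calls 12.4% were unchanged genes (8.5 to 13.2% over 9 other seeds), above the nominal rate, while 4.9% of unchanged genes had an unadjusted p under 0.05. The number of planted changes does not account for this excess, since the Benjamini-Hochberg adjustment is meant to hold the share whatever that number. The smallest p-values may therefore be too small, also in the data. How large the share is among the 4228 calls was not measured, because far fewer genes changed in the simulation. The list with planted changes was called and 0 of 40 lists without changes were. Simulated genes were drawn independently of each other, while the correlation estimated within the tested lists reached 0.424 (G2/M). The 0 of 40 therefore does not show how often camera calls correlated lists without changes. A planted length trend had a rank correlation with the fold changes of 0.825 before and 0.016 after the correction.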

Results

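C2C12 is a mouse myoblast line whose cells stop dividing and fuse into contractile myotubes when serum is lowered. Lenvatinib is an oral anticancer drug that inhibits the receptor tyrosine kinases of the vascular endothelial growth factor (VEGF) and fibroblast growth factor (FGF) families, platelet-derived growth factor receptor alpha, KIT and RET. RNA sequencing compared C2C12 cells that had differentiated for 4 days in horse serum with 1 µM lenvatinib and without it, with 3 libraries per group. The gene counts of the untreated libraries summed to 26597093, 25529288 and 28886472, and those of the lenvatinib libraries to 24585849, 24566768 and 32406563. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. They also do not say whether untreated cells received the drug's solvent or when lenvatinib was added, so every value compares the groups as labelled. Expression is given as CPM, a gene's counts relative to its library's total scaled with TMM factors, as mean ± SD over n = 3 libraries. Fold changes are lenvatinib over untreated on the log2 scale with the SE of the edgeR quasi-likelihood fit, and adjusted p-values are Benjamini-Hochberg values over the 14989 rows tested. Chromosome positions are those of the deposited table, whose build differs from the mm10 named in the submitters' processing notes.

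The comparison asks which transcripts differed between lenvatinib-treated and untreated differentiating muscle cells. With lenvatinib, 20 of 31 extracellular matrix genes rose and 5 fell, and 10 of 15 genes of the smooth muscle type cytoskeleton rose and 1 fell; the gene set test camera called both lists higher, but not with an estimated correlation (adjusted p = 0.092 and 0.223). Of interferon-stimulated genes 13 of 19 fell, and of ERK feedback genes 10 of 18 fell and 1 rose; camera called both lower, but not with an estimated correlation (adjusted p = 0.185 and 0.249). Transcripts of the osteoblast marker Spp1 and the secreted bone morphogenetic protein (BMP) antagonist Grem1 were lower. Of 44 sarcomere genes 10 rose and 10 fell, and the list was not called. In total 4228 of 14989 rows (28.2%) passed an adjusted p of 0.05, 1999 of them higher and 2229 lower with lenvatinib. Most changes were small, with a median of 1.17-fold among the risen genes and 1.21-fold among the fallen genes, and 408 genes changed at least 2-fold (130 up, 278 down). The groups did not overlap in 6010 rows (40.1%), where chance alone gives 10%. The first principal component of log2 CPM held 75.3% of the variance and separated the groups.

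Grem1 had the smallest p of all rows. Its transcript, on chromosome 2 from 113576509 to 113588991, fell from 479.5 ± 7.81 to 96.7 ± 2.21 CPM, 4.96-fold lower (-2.31 ± 0.03, adjusted p = 8.49e-41). Spp1, which encodes the bone matrix protein osteopontin (chromosome 5, 104582984 to 104588916), fell from 1544 ± 21.8 to 409.5 ± 15.7 CPM (-1.92 ± 0.03, adjusted p = 3.96e-39). Mgp, encoding an inhibitor of calcification, fell from 548 ± 9.67 to 211 ± 0.237 CPM, and the interferon-inducible Ifitm3 from 155 ± 3.65 to 66.1 ± 2.78 CPM. Myh4, the fast type IIb myosin heavy chain, fell from 634 ± 20.6 to 329 ± 6.37 CPM, 1.93-fold lower. Steep falls under the same rule were in Cd53, a leukocyte tetraspanin, from 7.65 ± 1.27 to 0.388 ± 0.0576 CPM (-4.27 ± 0.21) and in the chemokine Ccl8 (-3.40 ± 0.20). Acsbg1, an acyl-CoA synthetase, fell by 2.55 on the log2 scale, and Cyp11a1, the enzyme that starts steroid hormone synthesis, by 2.22. Hmga2, a chromatin protein of growing cells, fell from 65.4 ± 1.505 to 14.6 ± 1.83 CPM. The interferon-inducible GTPase genes Gvin1 and Gvin2 fell by 2.39 and 2.41, but they are near-identical copies between which counting can split reads, so their values are not independent. Olfr805, which fell by 2.18, carries an olfactory receptor's name, and reads of an overlapping transcript cannot be excluded because the strand setting of the counting is not given in the sources used here.

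Among the rising genes Col8a2, a network-forming collagen on chromosome 4 (126180586 to 126208123), rose from 31.9 ± 0.847 to 144 ± 4.76 CPM, 4.504-fold higher (2.17 ± 0.04, adjusted p = 2.15e-35). Tagln, an actin-binding protein of smooth muscle, rose from 140.4 ± 4.81 to 372 ± 8.19 CPM (1.40 ± 0.03, adjusted p = 8.05e-33). The elastic fiber protein Fbln5 rose from 132 ± 3.14 to 280 ± 3.21 CPM, the tissue plasminogen activator Plat from 45.2 ± 1.91 to 118 ± 2.78 CPM, and the matrix proteoglycan Prelp from 74.4 ± 4.12 to 247 ± 8.49 CPM. The largest rise among the genes that met the naming rule was in Megf6, from 0.502 ± 0.197 to 7.49 ± 0.624 CPM, 15-fold higher (3.91 ± 0.20). Npr3, the natriuretic peptide clearance receptor, rose 7.58-fold to 17.3 ± 0.864 CPM. The leucine-rich matrix proteoglycans Omd and Fmod rose 5.63-fold and 5.6-fold. Further rises were in the collectin Colec10 (4.61-fold), the collagen-binding integrin Itga1 (4.401-fold), the carbonic anhydrase Car3 (4.34-fold), the adhesion molecule Mcam (4.25-fold) and the matricellular protein Ccn3 (4.11-fold). In each of these genes every lenvatinib library lay beyond every untreated library, as the naming rule requires.

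**Figure D1:**
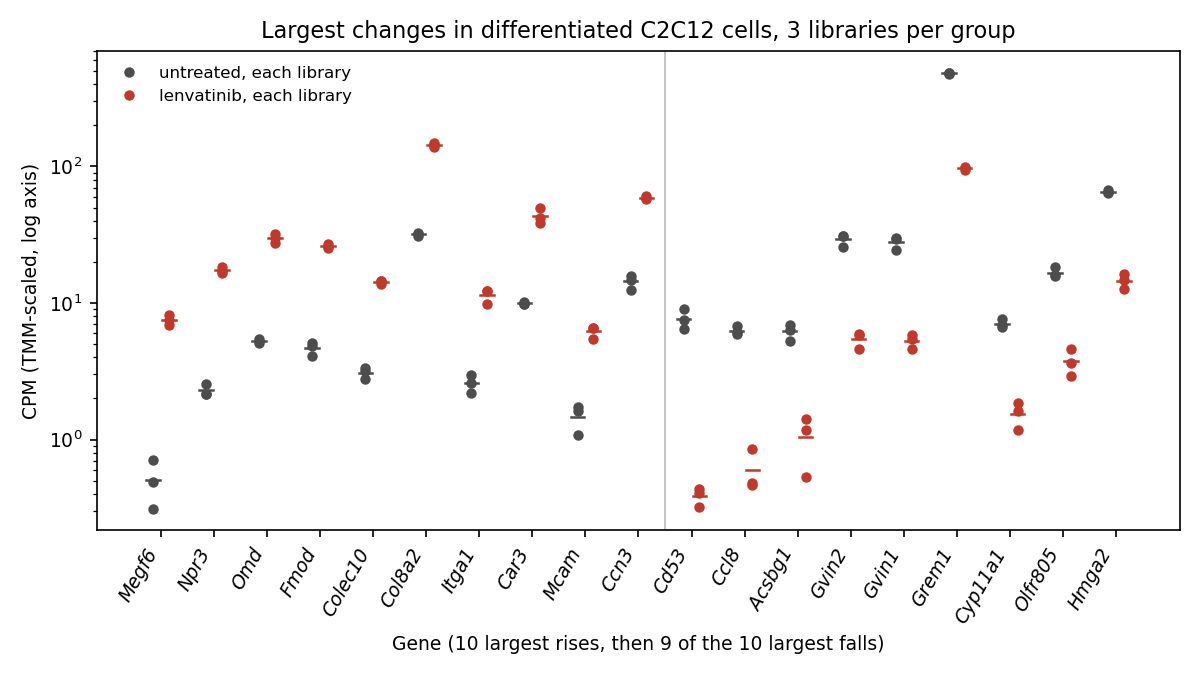
CPM (log axis) of the 10 genes with the largest rise and 9 of the 10 with the largest fall among those that met the naming rule; points are single libraries and bars the means of 3. Grem1 drops from 479.5 to 96.7 CPM and Col8a2 climbs from 31.9 to 144 CPM. The naming rule admits only genes whose groups do not overlap, so none of the 19 genes has overlap.

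The kinases that lenvatinib inhibits were examined at the transcript level. Of 10 target kinases, 7 had enough counts for a test, and 3 changed over all genes tested (also 3 when adjusted over the list alone). Fgfr1, on chromosome 8 from 26003670 to 26065734, was the most abundant and fell from 257 ± 10.5 to 172 ± 1.16 CPM (-0.58 ± 0.03, adjusted p = 2.01e-19). Pdgfra fell from 15.4 ± 0.961 to 11.6 ± 0.617 CPM (-0.41 ± 0.08, adjusted p = 8.11e-05), and Fgfr2 rose from 4.23 ± 0.742 to 7.25 ± 1.11 CPM (0.77 ± 0.13, adjusted p = 1.87e-05). Fgfr4 was at 11.4 ± 1.26 and 12.98 ± 0.0555 CPM and Fgfr3 at 8.58 ± 1.31 and 8.95 ± 1.11 CPM without and with lenvatinib, and neither passed the test (adjusted p = 0.109 and 0.661). Flt1, a VEGF receptor, was at 1.43 ± 0.121 and 1.28 ± 0.669 CPM and Ret at 0.653 ± 0.14 and 0.483 ± 0.114 CPM (adjusted p = 0.672 and 0.389). Kdr, the main VEGF receptor of endothelium, had 0 counts in 5 libraries and 2 counts in the third lenvatinib library. Flt4 and Kit had 0 counts in all 6, where a floor of 3 counts corresponds to 0.0926 to 0.122 CPM per library. Even the ribosomal protein gene Rps10 had only 0 to 8 counts in this table, so a row at or near 0 is not read as an absent transcript. The list as a set was not called (camera adjusted p = 0.279).

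Feedback genes of the ERK pathway, which growth factor receptors induce, fell as a list. Of 18 tested members 10 fell, 1 rose and 7 did not pass (the same counts when adjusted over the list alone), with a median log2 fold change of -0.28 (camera adjusted p = 0.000338; adjusted p = 0.249 with an estimated correlation). The phosphatase gene Dusp4 fell from 62.99 ± 2.86 to 37.6 ± 0.934 CPM (-0.74 ± 0.04). The receptor signaling inhibitors Spry1, whose row is wider than the gene, and Spred1 fell by 0.53 and 0.45 on the log2 scale, and Phlda1 fell by 0.38. The member that rose was Ccnd1, which encodes cyclin D1, by 0.22. Immediate early genes went both ways, with 4 of 16 higher and 5 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.973, its direction higher although the median was -0.03). Klf2 rose by 0.73 and Jun by 0.45 on the log2 scale, while Junb fell by 0.36 and Egr3 by 0.16.

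Extracellular matrix genes rose, with the smallest camera p of the lists tested. Of 31 tested members 20 rose, 5 fell and 6 did not pass (21 rose and 6 fell when adjusted over the list alone), with a median log2 fold change of 0.43 (camera adjusted p = 1.05e-23; adjusted p = 0.092 with an estimated correlation). Timp3, an inhibitor of matrix metalloproteinases, rose from 452 ± 5.05 to 833 ± 9.51 CPM (0.88 ± 0.03). Col8a1 rose from 175 ± 4.29 to 318 ± 7.11 CPM and the collagen VI chain gene Col6a2 from 239 ± 2.56 to 371 ± 6.99 CPM, beside Fmod. The 5 members that fell were Fn1, which encodes fibronectin (-0.78 ± 0.13, adjusted p = 0.0143), Timp1 (-0.43), Thbs1 (-0.31), Bgn (-0.26) and Mmp14 (-0.21); they are named because so few fell, after their values were seen.

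The smooth muscle and TGF-beta lists were also higher. Of 15 tested genes of the smooth muscle and SRF cytoskeleton list, 10 rose, 1 fell and 4 did not pass (11 and 1 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 3.98e-14; adjusted p = 0.223 with an estimated correlation). Smooth muscle actin, Acta2, rose from 2119 ± 77.6 to 3207 ± 43.1 CPM, Myl9 from 62.03 ± 0.716 to 90.9 ± 4.69 CPM and Actg2 from 31.3 ± 1.37 to 50.2 ± 3.84 CPM, beside Tagln. In the TGF-beta and BMP signaling list 12 of 21 rose, 5 fell and 4 did not pass (15 and 5 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.00295; adjusted p = 0.249 with an estimated correlation). Ccn1 rose from 250.2 ± 12.9 to 458 ± 5.62 CPM and the activin antagonist Fst by 0.47 on the log2 scale. The fallen member with the smallest p was Grem1, which blocks BMPs outside the cell.

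Markers of other cell types formed several lists. Of 6 tested osteoblast markers 4 fell, none rose and 2 did not pass (4 fell and 1 rose adjusted over the list alone), with a median of -0.51 (camera adjusted p = 2.32e-08; adjusted p = 0.148 with an estimated correlation). With no filter, which lets in members with few counts, the median was -0.063 (camera adjusted p = 7.59e-10), and with a filter of 5 CPM too few members were left to test. Beside Spp1, the transcription factor gene Runx2 fell by 0.26, and Dmp1 and Phex, both near 2 CPM, fell by 0.76 and 1.04. Phex no longer passed without the second untreated library (adjusted p = 0.118) or the third lenvatinib library (adjusted p = 0.0869), and with DESeq2 the adjusted p was 0.0539 for Dmp1 and 0.053 for Phex. Of 6 tested chondrocyte and tenocyte markers 2 rose, 1 fell and 3 did not pass (the same adjusted over the list alone). Camera called this list higher (adjusted p = 0.000622; adjusted p = 0.185 with an estimated correlation) although its median was -0.11 and its mean 0.08. The median was 0.229 with no filter, 0.085 without the third lenvatinib library and -0.053 without the second untreated one. The cartilage protein gene Cilp rose from 59.2 ± 3.77 to 167 ± 8.77 CPM. The tendon transcription factor gene Scx rose from 263 ± 5.29 to 350.5 ± 12.8 CPM, and the joint lubricant gene Prg4 fell by 0.79. Fibroblast markers were not called (camera adjusted p = 0.116), with 4 of 8 higher and 2 lower (4 and 2 adjusted over the list alone): Mfap5 rose by 0.96, Ly6a by 0.29 and Cd248 by 0.34, and Pdpn fell by 0.26. Adipocyte, endothelial, macrophage and cardiomyocyte markers had 4, 2, 3 and 4 tested members, too few for a set test. In them Lpl rose (0.22), and Cebpa (-0.70) and Cd14 (-0.54) fell; these 3 are the members that passed and were chosen after their values were seen.

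Genes of the muscle program moved in both directions. Of 16 tested myogenic transcription factor genes 7 rose, 3 fell and 6 did not pass (the same adjusted over the list alone; camera adjusted p = 0.366). Myog, the factor of terminal differentiation, rose from 856 ± 10.2 to 1036 ± 14.1 CPM (0.28 ± 0.02, adjusted p = 6.51e-12) and Myod1 from 120.2 ± 4.02 to 142 ± 1.801 CPM (0.24 ± 0.03, adjusted p = 9.86e-08; the row of Myod1 is wider than the gene). Hes6 rose by 0.27, Mef2c fell from 324 ± 12.7 to 241 ± 7.79 CPM, and Myf6 was near 1 CPM in both groups (0.848 ± 0.188 and 0.943 ± 0.0881 CPM, adjusted p = 0.734). Of 14 tested fusion genes 6 rose, 3 fell and 5 did not pass (6 and 3 adjusted over the list alone; camera adjusted p = 0.566). The fusogen gene Mymk rose from 773 ± 31.4 to 871 ± 14.7 CPM (adjusted p = 3.56e-06), and its partner Mymx was at 118 ± 5.93 and 113 ± 1.83 CPM (adjusted p = 0.255). Cdon and Jam2 rose by 0.30 and 0.30, and Il4ra and Cav3 fell by 0.50 and 0.50 on the log2 scale. Of 44 tested sarcomere genes 10 rose, 10 fell and 24 did not pass (10 and 12 adjusted over the list alone), with a median of -0.03 (camera adjusted p = 0.566). Myh4 (above) had the smallest p of this list, Tmod1 and Tpm1 rose by 0.40 and 0.30, Myl4 fell by 0.28, and the embryonic myosin Myh3 rose from 5973 ± 138 to 6386 ± 71.8 CPM (0.10 ± 0.02, adjusted p = 0.000377). Creatine kinase, Ckm, rose from 329.9 ± 2.16 to 365 ± 8.91 CPM (adjusted p = 4.06e-05). Acta1, the skeletal muscle actin, was not analysed here.

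**Figure D2:**
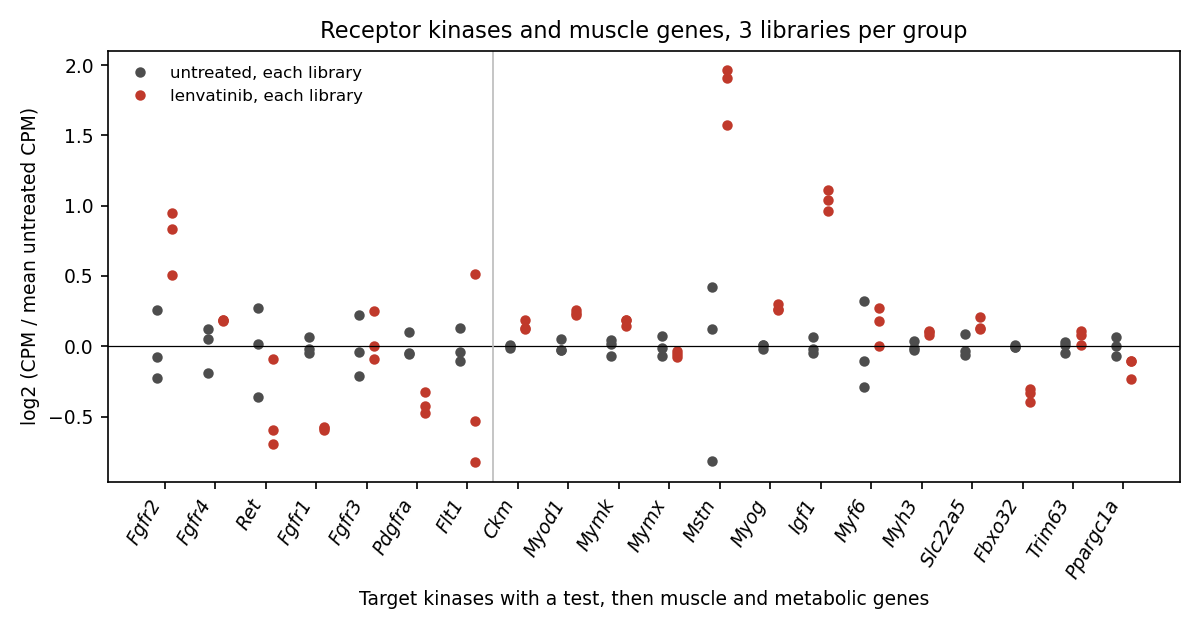
log2 ratio of each library's CPM to the untreated mean for 7 target kinases and 13 muscle and metabolic genes fixed beforehand; points are single libraries. The 3 lenvatinib libraries sit below the untreated ones for Fgfr1, Pdgfra and Fbxo32 and above them for Fgfr2, Myog, Myod1 and Igf1.

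Other lists of muscle structure were not called. In the calcium handling list 7 of 19 rose and 5 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.602); Cacna1s and Trdn rose by 0.23 and 0.28, and Camk2a and Casq1 fell by 0.27 and 0.69. At the neuromuscular junction 7 of 13 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.115), among them Dok7 (0.39), Chrna1 (0.17), Chrnb1 (0.18) and Colq (0.42), all higher. In the dystrophin complex 4 of 15 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.568); Dmd fell from 34.1 ± 3.13 to 21.4 ± 1.56 CPM, and Sspn, Sntb1 and Sgcd rose by 0.28, 0.24 and 0.27. Of 17 tested reserve cell and Notch genes 4 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.707, direction lower although the median was 0.02); Vcam1 and Notch3 fell by 0.73 and 0.71, and Notch1 and Jag1 rose by 0.49 and 0.56.

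Energy metabolism was covered by several lists. Of 75 tested nuclear genes of oxidative phosphorylation (OXPHOS) 32 rose, 3 fell and 40 did not pass (37 and 3 adjusted over the list alone), with a median log2 fold change of 0.08 (camera adjusted p = 0.000646; adjusted p = 0.249 with an estimated correlation). Atp5b rose from 1382 ± 20.5 to 1543 ± 6.95 CPM, Atp5o by 0.20 and Ndufa12 by 0.26, and Cox6a2, a muscle isoform, fell by 0.38. In glycolysis 13 of 21 rose, 1 fell and 7 did not pass (14 and 1 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.00865; adjusted p = 0.366 with an estimated correlation). Ldha, Pfkp, Gpi1 and Aldoa rose by 0.21, 0.29, 0.20 and 0.15. In the glycogen and creatine list 8 of 17 rose, 3 fell and 6 did not pass (9 and 3 adjusted over the list alone; median 0.09, camera adjusted p = 7.82e-05; adjusted p = 0.249 with an estimated correlation). The creatine kinase Ckb rose from 215 ± 5.81 to 345 ± 5.92 CPM, the creatine synthesis genes Gamt and Gatm by 0.87 and 0.28, and the glycogen phosphorylase Pygm by 0.22. The tricarboxylic acid (TCA) cycle list was not called (8 of 19 higher, 2 lower; 8 and 2 adjusted over the list alone; camera adjusted p = 0.143); Mdh2, Idh2 and Pdhb rose by 0.17, 0.17 and 0.14.

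Carnitine and fatty acid genes were not called as lists. Of 11 tested carnitine genes 2 rose, none fell and 9 did not pass (1 rose adjusted over the list alone; camera adjusted p = 0.419). The mitochondrial basic amino acid carrier Slc25a29 rose by 0.44 and Crot by 0.15 (adjusted p = 0.0461). Crot no longer passed without the second or the third untreated library (adjusted p = 0.145 and 0.116), without the first lenvatinib library (adjusted p = 0.369) and in 3 other settings. The carnitine transporter gene Slc22a5 was at 12.1 ± 0.681 CPM without and 13.4 ± 0.442 CPM with lenvatinib (0.15 ± 0.08, adjusted p = 0.165). The muscle carnitine palmitoyltransferase Cpt1b was listed at 0 in all 6 libraries, as was Gm44502, whose row covers the whole of Cpt1b on the same strand, so reads shared by the 2 rows may have been left uncounted and the 0 does not show that the transcript was absent. Of 23 tested fatty acid oxidation genes 5 rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.999); the fatty acid transporters Slc27a1 and Cd36 fell by 0.82 and 0.24, Acadl fell by 0.24, and Ucp2 rose by 0.25. Of 23 tested genes of mitochondrial biogenesis and dynamics 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.999). Esrrg, near 1 CPM, rose by 0.90, Pprc1 fell by 0.17, and Ppargc1a was at 2.26 ± 0.104 and 2.04 ± 0.103 CPM (adjusted p = 0.624). Of the mitochondrially encoded genes 3 had a test and none passed, and the row named mt-Co1 is wider than that gene.

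Genes of protein breakdown moved in different ways. Of 22 tested atrophy genes 7 rose, 6 fell and 9 did not pass (8 and 6 adjusted over the list alone; camera adjusted p = 0.917, its direction higher although the median was -0.03). Fbxo32, the atrophy-linked ubiquitin ligase atrogin-1, fell from 95.9 ± 0.653 to 75.7 ± 2.51 CPM (-0.34 ± 0.04, adjusted p = 2.68e-10), and Trim63, the ligase MuRF1, was at 48.4 ± 1.34 and 50.7 ± 1.69 CPM (adjusted p = 0.277). Mstn, the muscle growth inhibitor myostatin, rose from 0.207 ± 0.0819 to 0.735 ± 0.102 CPM (adjusted p = 0.00108), a low level. Ctsl and Gadd45a fell by 0.16 and 0.14, and Eif4ebp1 rose by 0.18. In the autophagy and lysosome list 14 of 28 fell, none rose and 14 did not pass (the same adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.00865; adjusted p = 0.338 with an estimated correlation). The cathepsin genes Ctsb and Ctsd fell by 0.34 and 0.20, the autophagy receptor Nbr1 by 0.24 and Gabarapl1 by 0.23. Of 31 tested proteasome genes 5 rose and none fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.162), among them Psma3 (0.12).

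Stress and growth pathways gave several small shifts. Of 26 tested integrated stress response genes 17 rose, 2 fell and 7 did not pass (20 and 2 adjusted over the list alone; median 0.18, camera adjusted p = 0.000211; adjusted p = 0.27 with an estimated correlation). The regulator Atf4 rose from 338 ± 3.82 to 405 ± 3.89 CPM, Mthfd2 by 0.29 and Sesn2 by 0.43, and the cytokine Gdf15 rose from 5.03 ± 1.09 to 9.47 ± 0.644 CPM. In the NRF2 target list 9 of 19 rose, 2 fell and 8 did not pass (11 and 2 adjusted over the list alone; median 0.14, camera adjusted p = 0.0149; adjusted p = 0.366 with an estimated correlation). Gsta4, Me1, Fth1 and Gclc rose by 0.72, 0.31, 0.17 and 0.40. This call was lost without the third untreated library (adjusted p = 0.0518) and with a filter of 5 CPM (adjusted p = 0.0564). In the IGF and insulin signaling list 8 of 17 rose, 6 fell and 3 did not pass (10 and 6 adjusted over the list alone; median 0.09, camera adjusted p = 0.0378; adjusted p = 0.366 with an estimated correlation). Its call was lost without the third untreated library (adjusted p = 0.0518), without the second lenvatinib library (adjusted p = 0.0648) and in 2 other settings (adjusted p = 0.122 and 0.0567). The growth factor Igf1 rose from 35.2 ± 1.43 to 72.3 ± 3.81 CPM (1.04 ± 0.05, adjusted p = 1.08e-21). Its binding protein genes Igfbp2 and Igfbp3 rose by 0.72 and 1.38, and Igfbp4 fell by 0.71. The related growth factor gene Igf2, with 0 to 5 counts per library, had no test, and such a row is not read as an absent transcript.

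Genes of the G1/S step of the cell cycle rose. Of 20 tested G1/S genes 18 rose, none fell and 2 did not pass (19 rose adjusted over the list alone), with a median of 0.28 (camera adjusted p = 3.09e-07; adjusted p = 0.249 with an estimated correlation). The cyclin E genes Ccne2 and Ccne1 rose from 6.298 ± 0.506 to 12.03 ± 1.67 CPM and from 7.99 ± 0.659 to 12.7 ± 0.223 CPM, and the replication licensing genes Cdc6 and Mcm2 rose by 0.83 and 0.34. Of 28 tested G2/M genes 4 rose, 1 fell and 23 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.389, and 0.0282 without the first untreated library). Top2a, the DNA topoisomerase of dividing cells, rose by 0.31, Cdk1 and Aurkb rose by 0.20 and 0.28, and Cdc20 fell by 0.22. The calls of Cdk1, Aurkb and Cdc20 were lost in 3, 2 and 3 settings (highest adjusted p = 0.0766, 0.0838 and 0.0666). Whether the G1/S and G2/M lists differed from each other was not tested. In the list of replication-dependent histones 11 of 36 fell, none rose and 25 did not pass (the same adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.0146; adjusted p = 0.224 with an estimated correlation). The linker histone gene H1f2 fell from 146 ± 2.01 to 118 ± 3.69 CPM, and H2ac18, H4c17 and H4c18 fell by 0.32, 0.33 and 0.84. The rows of H2ac18 and H4c17 are wider than these genes and may hold other reads. Core histone genes are near-identical copies, so reads can be split between them. Ribosomal protein genes fell slightly: 38 of 83 fell, 2 rose and 43 did not pass (42 and 2 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.00322; adjusted p = 0.338 with an estimated correlation). Rpl10a, Rps14, Rps26 and Rps3 fell by 0.21, 0.18, 0.18 and 0.14, and processed pseudogenes of this family can take part of the reads.

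Interferon-stimulated genes fell. Of 19 tested members 13 fell, none rose and 6 did not pass (the same adjusted over the list alone), with a median log2 fold change of -0.58 (camera adjusted p = 1.1e-05; adjusted p = 0.185 with an estimated correlation). Lgals3bp fell from 33.4 ± 3.38 to 17.5 ± 0.134 CPM (-0.93 ± 0.07), the antiviral tetherin gene Bst2 from 10.9 ± 1.07 to 6.14 ± 0.944 CPM, Ifi27 from 67.4 ± 5.01 to 55.7 ± 0.584 CPM and Oasl2 from 2.92 ± 0.749 to 1.27 ± 0.119 CPM. With a filter of 5 CPM the median was -0.3 (camera adjusted p = 0.00278). Macrophages are cells in which many of these genes are active. Of their 3 tested markers Cd14 fell (above), from 5.11 to 3.52 CPM. Lyz2 (1.09 CPM without and 1.49 CPM with lenvatinib) and Cd68 (0.527 and 0.612 CPM) did not pass. The summed CPM of all 10 macrophage genes, of which Cd14 was the most abundant, was 6.93 ± 0.31 without and 5.83 ± 0.17 with lenvatinib. In the NF-kB and cytokine list 6 of 16 fell, 2 rose and 8 did not pass (the same adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.0233; adjusted p = 0.249 with an estimated correlation). The chemokines Ccl7 and Cxcl5 fell from 4.43 ± 0.568 to 0.919 ± 0.241 CPM and from 3.24 ± 0.48 to 1.12 ± 0.201 CPM, Il1b fell by 2.15 and the NF-kB inhibitor Tnfaip3 by 0.34. This call was lost with a filter of 5 CPM (adjusted p = 0.65), which takes out the low cytokine genes, and the median was -0.147 without the third untreated and -0.148 without the second lenvatinib library.

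**Figure D3:**
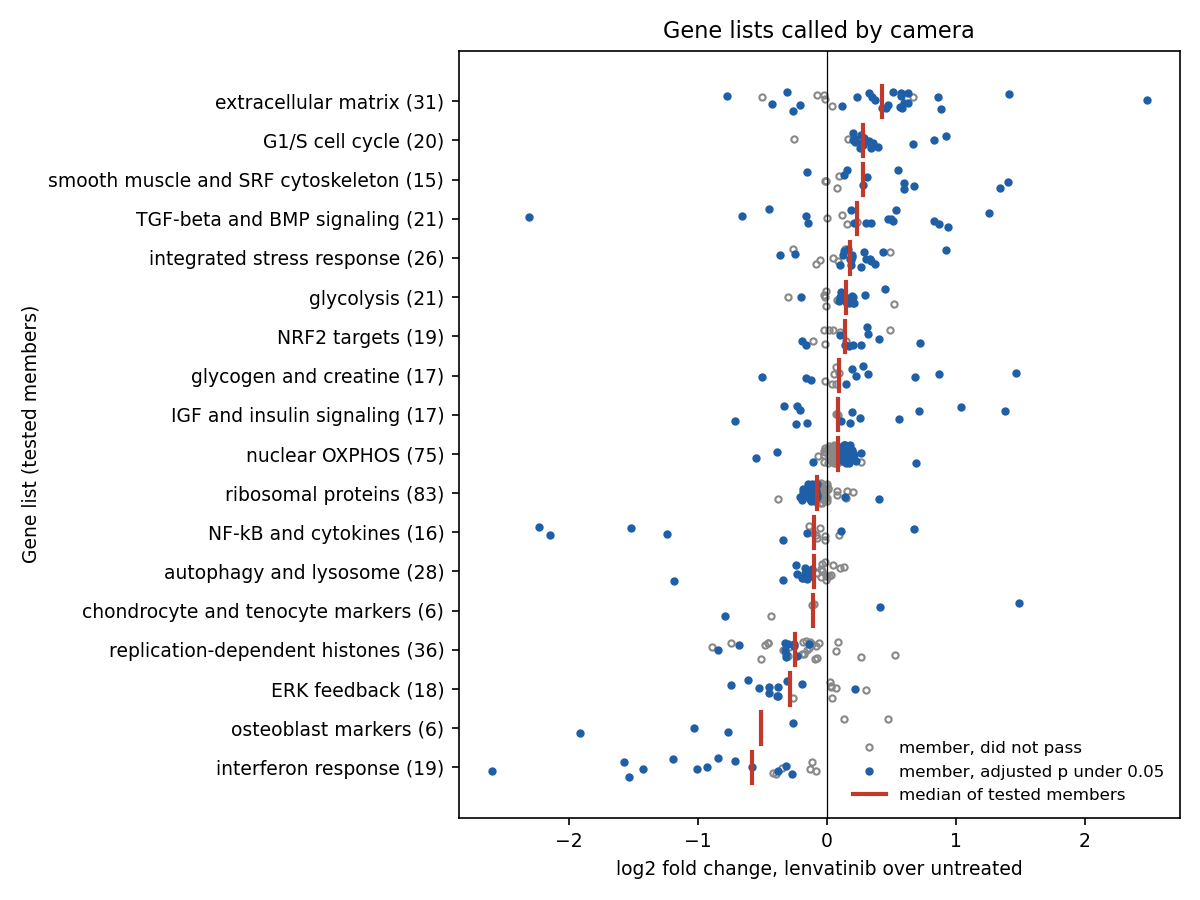
log2 fold change, lenvatinib over untreated, of every tested member of the 18 lists that camera called; filled points passed the test, open points did not, and red bars are medians. Extracellular matrix genes have the highest median (0.43) and interferon genes the lowest (-0.58).

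Of the remaining lists none was called. For ER chaperones 6 of 19 rose and none fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.162), with Herpud1, Hyou1 and Dnajc3 higher by 0.21, 0.17 and 0.16 on the log2 scale. For heat shock genes 5 of 14 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.602); Hspa1b and Hspa1a fell by 0.34 and 0.31, near-identical copies, and Hsph1 rose by 0.18. For p53 targets 2 of 20 rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.549); Cdkn1a fell from 1935 ± 35.3 to 1689 ± 19.1 CPM, Pmaip1 fell by 0.22, and Plk2 rose by 0.12. For cholesterol synthesis 4 of 22 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.761). For lipogenesis 4 of 18 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.556), with Plin2 and Scd1 falling by 0.30 and 0.23 and Scd2 rising by 0.11. For hypoxia and angiogenic factors 8 of 21 rose and 4 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.296); Ndrg1 and P4ha1 rose by 0.53 and 0.33, and Angpt1 and Egln3 fell by 0.48 and 0.41. For thyroid hormone genes 2 of 6 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.389). For the xenobiotic and AhR response 3 of 12 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.999), with Aldh1a3 higher by 0.86 and Por lower by 1.18-fold.

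In all, camera with a preset correlation of 0.01 called 18 of the 43 lists tested, 11 higher and 7 lower. With the correlation estimated per list none was called (0 of 43), where fry's directional test, which does not compare a list with other genes, called 29.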

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

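The alternatives without rows wider than the gene, with named genes only and with the GC and length correction were chosen after seeing the data. Over 17 other scalings, filters, tools, leave-outs and row sets with a full gene test, the count of changed genes lay between 3021 (DESeq2) and 4418 (GC and length correction), against 4228. Leaving out 1 library at a time gave 3618 to 3797 genes. Only the thresholds on size moved it by more than 1.5 times: a fold change of at least 2 left 408 genes (130 higher, 278 lower), and glmTreat against a fold change of 1.2 left 972 (380 higher, 592 lower), both by construction. The 18 called lists became 0 with an estimated correlation, 29 with fry and 16 to 19 over the leave-outs. With a filter of 5 CPM 13 of 41 were called, 3 were lost and 2 called ones were left without a test. With an estimated correlation both the estimate and camera's test rest on 4 residual degrees of freedom, which by itself raises the p-values. How much of the loss came from this and how much from the estimates was not tested. The NF-kB, histone and chondrocyte lists were lost although their estimates (-0.048, -0.002 and -0.183) lay below the preset 0.01. For these lists a higher correlation is therefore not the cause. No called gene or list reversed. Of 3293 values of 195 called genes 35 lost the call, and 12 uncalled genes changed side in 3 of 200 values (Mymx passed with the GC and length correction). With no filter the lists of the neuromuscular junction, TCA cycle, proteasome, ER chaperones and fibroblast markers were also called.

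The replicate numbers do not pair the samples: deviations from the group means of same-numbered libraries correlated by 0.022, -0.078 and -0.004. With the replicate block 4134 genes (1952 higher, 2182 lower) and 18 lists were called.

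Among uncalled results the sign turned in these alternatives, given as log2 fold changes. Over the leave-outs Fgfr3 ranged from -0.037 to 0.196 and Flt1 from -0.655 to 0.037. For lists, camera's direction turned in each setting named below and in some of the leave-outs. The medians follow, and the leave-out ranges also cover leave-outs in which the direction did not turn. The median of mitochondrial biogenesis was 0.007 with upper quartile factors, 0.006 with no filter, 0.009 with the GC and length correction and -0.014 to 0.008 in leave-outs. That of fatty acid oxidation was 0.025 with a filter of 5 CPM, 0.011 with the correction, 0.032 with fry and 0.015 to 0.055 in leave-outs. Muscle atrophy gave -0.035 with the 5 CPM filter. Immediate early genes gave -0.04 with the correction and -0.059 to -0.003 in leave-outs. The xenobiotic list gave 0.026 with RLE factors, -0.101 with the 5 CPM filter, 0.028 without wide rows and with named genes only, 0.018 with the correction, 0.027 with fry and -0.051 to 0.007 in leave-outs.

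Depth limits mainly the low genes: several interferon and cytokine genes lie near 1 to 5 CPM. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05: the real split called 4228 genes and 18 lists, 1 split each, and the highest other 1 gene and 10 lists. Every other split mixes treated and untreated libraries, so the group difference adds to its spread. Few gene calls were therefore fixed in advance, and these splits are not comparisons without the drug.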

Other observations

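The gene families below, the test of myotube share and the test of macrophages were chosen only after the result was seen; the other tests were set beforehand. Among 11 tested small leucine-rich proteoglycans, which bind collagen fibrils, 6 rose, 1 fell and 4 did not pass. Ogn, the most abundant of those that rose, went from 756 ± 9.56 to 1370 ± 57.8 CPM, Aspn rose by 0.41 and Ecm2 by 0.66 on the log2 scale, beside Prelp, Omd and Fmod, while Bgn fell from 2349 ± 72.2 to 1960 ± 18.9 CPM and Dcn was at 68.6 ± 4.54 and 65.02 ± 0.633 CPM (adjusted p = 0.174). Of 5 CCN matricellular genes 4 rose: Ccn2 from 184 ± 14.1 to 439 ± 3.12 CPM, Ccn5 from 15.1 ± 0.0628 to 45.1 ± 1.83 CPM, Ccn1 and Ccn3; Ccn4 was at 430.3 ± 4.64 and 422 ± 10.1 CPM (adjusted p = 0.483). Of 31 collagen genes 16 rose and 3 fell. The fallen ones, Col13a1 (-0.94), Col25a1 (-1.11) and Col28a1 (-1.48), lay under 16 CPM, and the abundant Col3a1 was at 2573 ± 44.1 and 2542 ± 42.7 CPM (adjusted p = 0.636). With library size only, Col6a3 also fell, making 4. The other family counts were equal under the 4 scalings.

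Of 6 tested CC chemokine genes 5 fell and none rose: Ccl8 and Ccl7, Ccl2 from 2.54 ± 0.402 to 1.05 ± 0.248 CPM, Ccl9 from 1.51 ± 0.328 to 0.698 ± 0.143 CPM and Ccl11 from 0.794 ± 0.325 to 0.0718 ± 0.064 CPM. Of 12 interferon-inducible GTPase genes from several families 5 fell and none rose. Beside Gvin1 and Gvin2, Irgm1 fell from 42.5 ± 0.995 to 34.8 ± 1.51 CPM. Tgtp1 and Tgtp2, near-identical copies, fell from under 2 CPM. The tested Gbp genes and Mx2 did not pass. Among 19 semaphorin genes 7 fell and 3 rose. The axon guidance genes Sema5a and Sema7a fell from 82.8 ± 1.74 to 29.4 ± 1.67 CPM and from 71.7 ± 0.844 to 31.9 ± 1.05 CPM, and Sema3c rose from 61.03 ± 3.24 to 107 ± 3.94 CPM.

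Of 31 extracellular matrix genes 20 rose and 5 fell with lenvatinib (camera adjusted p = 1.05e-23; adjusted p = 0.092 with an estimated correlation). A lower share of myotubes would raise matrix and mesenchymal marker genes alike. Of 51 tested members of 4 such lists 26 rose and 12 fell, with Spp1, Timp1 and Bgn among the abundant ones that fell. These falls were known when the test was set, and falls of single genes do not measure myotube share, so the test cannot decide. Of 44 sarcomere genes 10 rose and 10 fell, and that list was not called (camera adjusted p = 0.566). A GC or length trend as the whole cause is argued against by the median of 0.405 that the list kept after the correction. What stays open, as a hypothesis, is a drug effect on matrix genes in myoblasts or myotubes, which was not tested. A lower share of myotubes and a change confined to 1 mesenchymal cell state are not excluded either. Which of the cells made these transcripts cannot be read from bulk RNA.

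Of 19 interferon genes 13 fell, none rose and 6 did not pass with lenvatinib (camera adjusted p = 1.1e-05; adjusted p = 0.185 with an estimated correlation). The sample titles name only C2C12 cells, a myoblast line, and no macrophages. From these counts, loss of contaminating macrophages still cannot be told apart from a change within the muscle cells. Only 3 of 10 macrophage genes had a test. Another 4 (Adgre1, C1qa, C1qb and Tyrobp) had 0 counts in all libraries, but rows near 0 are not dependable in this table. Cd14 (-0.54) and the leukocyte gene Cd53 (-4.27) fell. The other 2 tested macrophage genes, Lyz2 and Cd68, did not pass. Their means were 1.09 and 0.527 CPM without and 1.49 and 0.612 CPM with lenvatinib. The summed CPM of the 10 genes fell by 1.94% of the fall in the interferon genes' sum, or 14.8% with Cd53. The list's median was -0.508 or lower in each of the 6 leave-outs and -0.575 after the GC and length correction, which argues against a single library or such a trend as the whole cause, and it was -0.3 with a filter of 5 CPM. What stays open, as a hypothesis that no table here tests, is also a drug effect on these genes in the muscle cells.

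Of 83 ribosomal protein genes 38 fell and 2 rose, and of 36 replication-dependent histone genes 11 fell; both list calls were lost with an estimated correlation (adjusted p = 0.338 and 0.224). The ribosomal median was -0.095 after the GC and length correction and -0.066 or lower under each of 4 scalings, but the scalings shifted the median of all genes by only 0.008, so they decide nothing. The histone median was -0.264 after the correction. Replication-dependent histone mRNA has no poly(A) tail, and less carry-over of such RNA cannot be told apart from a change in histone transcripts, since only 3 other genes of that kind had a test (median -0.365, none past the threshold). Carry-over also presumes poly(A) selection, which the sources used here do not give. The name pattern of the list also admits the linker histone gene H1f0, which is not replication-dependent.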
